A study of Arabidopsis thaliana with 6 samples.

How the data were processed

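The series holds 6 libraries of messenger RNA from whole seedlings of Arabidopsis thaliana, 3 of the activation-tagging mutant cog1-2D and 3 of the Col-0 wild type. Seedlings were 7 days old, grown on MS medium in long days at 23 °C and not treated, per the labels' protocols. RNA was extracted with the NucleoSpin RNA II kit and libraries were made with the TruSeq Stranded mRNA kit, per the labels' protocols. The labels and the column names of the deposited table gave each library's genotype and replicate number, and every library was used.

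The authors' tools were Trimmomatic 0.36, HISAT2 2.1.0, Cufflinks 2.2.1 and Cuffdiff on the build TAIR10, per the labels. The role and order of each tool are not given in the sources used here, nor is the strand setting of the counting. The deposited table of all genes holds expected counts of fragments per gene and library, unscaled, per the file headers. It also holds FPKM values, fragments scaled by gene length and by 1 factor per library, per the file headers. Of the deposited expected counts, 98.1% were whole numbers within 1e-06, and the rest were fractions. A deposited workbook gives the authors' calls, with FPKM per genotype, the log2 fold change of cog1-2D over wild type and Cuffdiff's adjusted p-value or q-value, per the file headers. It lists 3124 genes, the largest q-value being 0.0498. Sheets of genes changed by 2-fold or more hold 293 higher and 572 lower genes.

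The table held 33617 genes, of which 32225 matched a locus tag of the TAIR10.1 reference, which gave strand, position, symbol and product. Coordinates are those of TAIR10.1. In all, 13428 genes were at 0 in every library. Total fragments per library ran from 10575945 to 11202122. Counting precision was expressed with exact binomial 95% intervals for ratios with 1 to 3 fragments in one group. For genes at 0 in one group a floor of 3 fragments over the summed group was used.

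The expected counts were rounded to whole numbers and compared between genotypes with edgeR 4.0.16 in R 4.3.3, using filterByExpr, TMM factors, the quasi-likelihood F-test and Benjamini-Hochberg adjustment at 0.05 over all 10347 genes that passed the filter. The only model term was the genotype. The common biological coefficient of variation was 0.0762. CPM values are fragment counts scaled to a common library size with TMM factors, and their errors are SD over 3 libraries. The standard error of a log2 fold change was computed as its size divided by the square root of the F statistic. Cuffdiff could not be rerun from the tables, so edgeR took its place.

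The tests, alternatives and 31 gene lists with 484 entries (473 genes) were chosen before the data were examined. Lists with at least 5 tested members, 24 in all, were tested with camera of limma 3.58.1. This used log2 CPM with a prior count of 2, a preset correlation between genes of 0.01, a two-sided test and Benjamini-Hochberg adjustment over the 24 lists. Alternatives for the lists were camera with an estimated correlation and fry, a test of whether a list's genes move one way on balance. The rule for naming genes covers COG1, PRX2, PRX25, PRX71, the CDF genes and the 5 measured genes nearest to COG1 on each side. Not all CDF genes and neighbours are named singly. The rule also covers the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 1 and no overlap between genotypes. From each list it takes up to 4 called members with the largest change, or up to 2 with the smallest p where none was called. It also takes all called class III peroxidases. Genes named outside this rule are described as chosen after their values were seen.

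Other settings tried were RLE and upper-quartile factors, DESeq2 1.42.0, no low-count filter, a mean of at least 50 counts, robust dispersion, and limma on log2 FPKM with pseudocounts of 1 and 0.1 for genes with a mean FPKM of at least 0.5. A replicate block and leaving out each library in turn were also tried. Plus-strand genes only, and leaving out genes nearly absent from one genotype, were added after seeing the data. The 10 splits of the 6 libraries into 3 against 3 were each fitted.

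Enrichment of called genes was tested with one-sided Fisher's exact tests for excess in scipy 1.17.1 on 208 process terms and product families of the reference with at least 10 members. The background was the 10136 tested plus-strand genes, and p-values were adjusted by the Benjamini-Hochberg method over both directions. This test was chosen after the calls were seen. A two-sided permutation test with 100000 resamples compared sets of root genes. Overlap of loci was found with bedtools 2.31.1. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and plots.

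The edgeR steps were tested on simulated counts for the comparison of cog1-2D with wild type, with 10233 genes tested, 200 of them changed. Of 100 genes changed by 1 on the log2 scale, 89 were called in the right direction, and of 100 changed by 0.5, 56 were. Of 10033 unchanged genes, 12 were called. In simulated lists of 10 genes, camera called the 1 list shifted by 0.5 and 0 of 20 random lists. In the real counts, splits that mixed the genotypes passed up to 5 lists in camera. Those splits keep part of the genotype difference. Neither they nor the simulated lists show how often camera errs on the lists used here. The enrichment step passed 0 terms with random calls, and with 1 term planted that term passed, among 5 in all.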

Results

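Messenger RNA was sequenced from whole 7-day Arabidopsis seedlings of 2 genotypes, with 3 libraries each. One genotype was the activation-tagging mutant cog1-2D, labelled as a mutant line in which an inserted tag is meant to raise expression of COG1. The other was the Col-0 wild type. COG1 encodes a Dof-type transcription factor known as a negative regulator of phytochrome responses. The replicates are numbered 0, 1 and 2 in the labels. The labels do not say whether they came from separate cultures, so every p-value below measures the spread between these samples only.

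The libraries labelled cog1-2D held 10672997, 10575945 and 11044670 fragments assigned to genes in replicates 0, 1 and 2. The wild type libraries held 11202122, 10748802 and 10686555. Between 15366 and 15681 genes had a value above 0 in the mutant libraries. The wild type libraries had 16433, 13123 and 16166 such genes. Genes with 10 or more fragments numbered 10445, 10111 and 10349 in the wild type libraries. The most abundant gene in each library was LHCB1.3 (also CAB1), a chlorophyll a/b binding protein of the photosystem II antenna, and it took at most 2.54% of the fragments of a library. Pearson correlations of log2 CPM (fragment counts scaled to a common library size) across genes lay between 0.986 and 0.994 within a genotype and between 0.928 and 0.934 across genotypes. These correlations are across genes, which are not independent replicates. The first principal component separated the genotypes and held 83.1% of the variance. The next held 7.38% and set wild type replicate 1 apart from the other libraries of its group.

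Genes on the minus strand of the reference were almost unmeasured in all 6 libraries. Nuclear protein-coding genes on the plus strand numbered 13777, with a median of 985 fragments over the 6 libraries. The 13666 on the minus strand had a median of 1 fragment. Of the fragments on both sets, 99.9% were on plus-strand genes and 0.135% on minus-strand genes. In wild type replicate 1 the minus-strand share was 0.0301%, against 0.139% to 0.169% in the other libraries. That library had 1616 minus-strand genes above 0, against 4769 and 4604 in wild type replicates 0 and 2. Much of its lower number of genes above 0 therefore lay on that strand. Among the abundant antenna and Rubisco small subunit genes, the 7 plus-strand members had a median of 7431 CPM and the 11 minus-strand members a median of 11.19 CPM. Of the 473 genes in the lists described here, 235 lie on the minus strand. Of these, 216 did not pass the low-count filter and 19 were tested at the low level left on that strand. Those tested were 11 antenna and Rubisco genes, 3 chlorophyll genes and 2 antioxidant genes. The peroxidase, clock and iron deficiency lists held 1 each. They are counted below among the genes that did not pass, which does not show that they were unchanged.

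**Figure D1:**
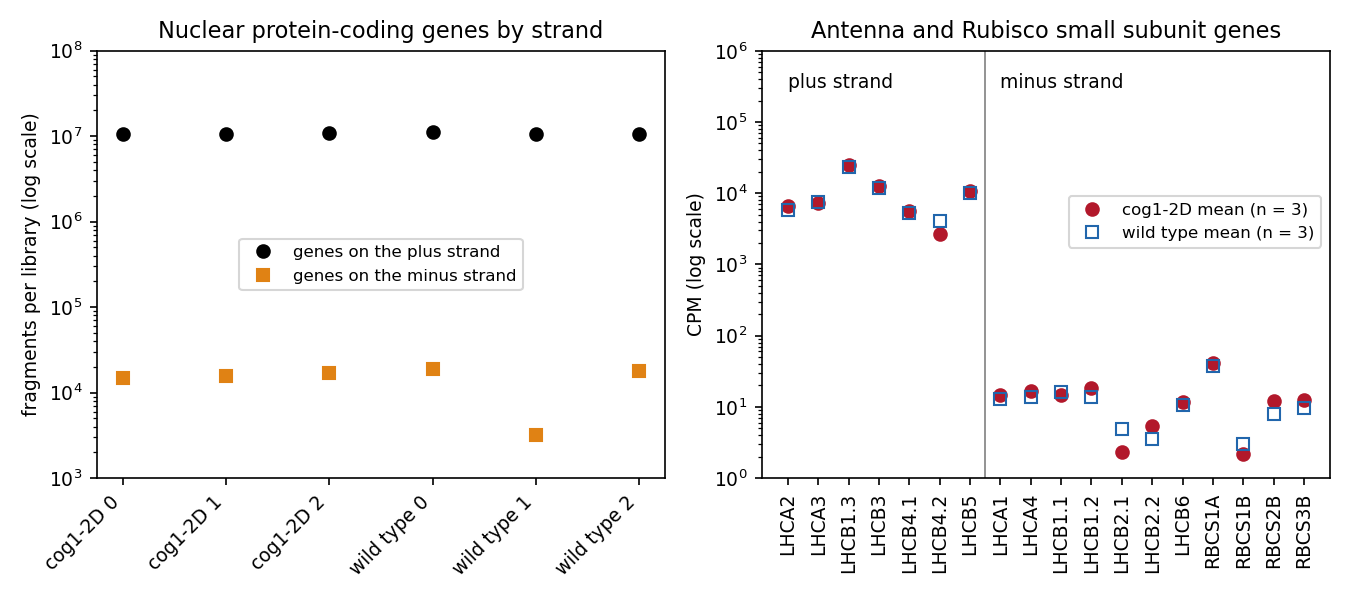
The left panel plots fragments per library (log scale) on nuclear protein-coding genes of each strand, and the right panel mean CPM (log scale, n = 3 libraries per genotype) of antenna and Rubisco small subunit genes by strand. Minus-strand genes held 3219 to 18872 fragments per library, and the minus-strand antenna and Rubisco genes lay far below the plus-strand ones in both genotypes.

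COG1 itself (AT1G29160, chromosome 1, 10183390 to 10184512 in TAIR10.1) lies on the minus strand and was not measurable. The libraries labelled cog1-2D held 0, 3 and 3 COG1 fragments, and each wild type library held 0. The genotype labels could therefore not be checked through COG1, and "cog1-2D" below means the libraries labelled so. The peroxidase genes in the title of the series were in the same position. PRX2 (AT1G05250) had 0 fragments in every library. PRX25 (AT2G41480) had 1, 1 and 2 fragments in the cog1-2D libraries and 0 in each wild type library, and PRX71 (AT5G64120) had 1, 2 and 7 against 3, 0 and 6. None of the 4 study genes passed the low-count filter. Without that filter, the fit with edgeR covered 3 of them and none passed, with adjusted p = 0.122 for COG1, 0.230 for PRX25 and 0.969 for PRX71. Only COG1 had an unadjusted p under 0.05 in that fit. DESeq2 did not call PRX71 and gave no adjusted p for COG1 or PRX25. Of the 5 CYCLING DOF FACTOR relatives of COG1, only CDF2 passed the low-count filter and was tested. The other 4 lie on the minus strand. CDF2 did not pass the test, over all genes or adjusted over the list alone, with a log2 fold change of -0.20 ± 0.14 (SE).

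The comparison asked which genes differ in seedlings between the mutant and the wild type, and it covered 10347 genes. In cog1-2D, 8 of 8 tested root hair genes, 6 of 7 suberin genes, 6 of 10 glucosinolate genes and 6 of 8 flavonoid genes fell, while 4 of 5 auxin response genes and 3 of 3 shade response genes rose. The 4 lists with falls passed limma's camera test with a preset correlation but not with an estimated one (adjusted p = 0.368, 0.660, 0.660 and 0.894 with an estimated correlation). The root hair gene PRP1 fell by 2.09 ± 0.19 on the log2 scale (SE, n = 3 per genotype), and the suberin fatty acyl reductase gene FAR5 fell by 1.502 ± 0.09. MYB29, a transcription factor of aliphatic glucosinolate synthesis, fell from 50.6 ± 4.7 to 12.5 ± 1.9 CPM (SD, n = 3). IAA29, an auxin and shade response gene, rose from 2.43 ± 0.47 to 10.3 ± 1.2 CPM. A further set of 100 genes had less than 1 part in 16 of their level in one genotype left in the other. Of the 74 lower in cog1-2D, 13 were disease resistance genes.

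With edgeR's quasi-likelihood test at a Benjamini-Hochberg false discovery rate of 0.05, 1686 genes were higher and 2066 lower in cog1-2D, which is 36.3% of the genes tested. Of these, 290 were higher and 596 lower by 2-fold or more. In 5154 genes, 49.8% of those tested, all 3 libraries of one genotype lay above all 3 of the other, where chance gives 10%. The called genes comprised 3731 on the plus strand, 18 on the minus strand and 3 with no strand in the reference. Without wild type replicate 1, the library that stood apart, 1481 genes were higher and 1890 lower.

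Of the 10 measured genes nearest to COG1, 5 on each side, 2 rose and 8 did not pass the test. Over all tested genes, 1686 of 10347 rose. All 10 neighbours lie on the plus strand, so neighbours on the minus strand were not covered. AT1G29120, 4.87 kb away, rose by 0.47 ± 0.05 on the log2 scale, from 65.4 ± 0.6 to 90.4 ± 3.3 CPM (SD, n = 3, adjusted p = 0.000161 in edgeR's test). AT1G29070, 32.0 kb away, rose by 0.19 ± 0.05, and that call was lost without cog1-2D replicate 1 or 2 or wild type replicate 2 (edgeR's test, adjusted p = 0.0694, 0.0541 and 0.0663). AT1G29040, which did not pass, did so without wild type replicate 2 (edgeR's test, adjusted p = 0.0399). The nearest gene, ATS9, at 0.582 kb, had a log2 fold change of -0.03 ± 0.05.

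The largest falls included several genes of pathogen recognition. ECS1, known for its expression in some Arabidopsis accessions and not in others, had 3 fragments over the cog1-2D libraries and 8274 over the wild type libraries. Scaled for library size, that is a ratio of 2719, with an exact 95% binomial interval of 930.2 to 13189. Of the 3 fragments, 2 were in cog1-2D replicate 1, and without that library the ratio was 5505 (988 to 217462). AT4G19500 had 1 fragment against 4244, a ratio of 4185 (751 to 165320). That fragment was in cog1-2D replicate 2, and without it the gene was at least 916-fold lower, against a floor of 3 fragments over the remaining libraries. DAR4 had 0 against 3386, at least 1113-fold lower in cog1-2D, counted against a floor of 3 fragments over the group. Such intervals and floors cover counting error only. Of the other seven genes with the largest falls, all had 0 fragments in cog1-2D. AT5G28919 was at least 598.5-fold lower, AT3G43740 at least 460-fold, AT4G01593 at least 424-fold and AT5G46510 at least 418-fold. AT5G51630 was at least 372-fold lower, AT5G51620 at least 275-fold and AT5G44572 at least 201-fold.

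The largest rises mostly had fewer fragments behind them than the largest falls. AT3G61030 had 929 fragments in cog1-2D and 0 in wild type, at least 314-fold higher, and AT3G60950 had 598 and 0, at least 202-fold higher. Bounds for AT4G12280, AT1G27570, AT5G34871, AT1G63540, AT5G44850 and AT4G07090 ran from at least 106.8-fold down to at least 54.4-fold higher. AT5G47260 had 290 fragments against 1, a ratio of 294 (52.4 to 11657), or at least 63.5-fold higher without wild type replicate 0, which held that fragment. PTAC18 had 692 against 1, a ratio of 702 (126 to 27760), or at least 159-fold higher without wild type replicate 1, which held that fragment. It lies on the minus strand, so these counts do not give its level in either genotype.

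A wider set of 100 genes had a mean of at least 5 CPM in one genotype and less than 1 part in 16 of it in the other, a definition chosen after the values were seen. Such genes are called nearly absent below, although JAL33, a lectin gene, kept 363 fragments in cog1-2D. By this definition, 74 were nearly absent from cog1-2D and 26 from wild type. Minus-strand genes, 188 of the 10347 tested, made up 0 of the 74 and 8 of the 26. The 74 lay on all 5 chromosomes, with 21, 8, 17, 8 and 20 genes on chromosomes 1 to 5. Genes of the nucleotide-binding leucine-rich repeat class, which encode intracellular immune receptors, made up 13 of the 74, and 3 of the 26 nearly absent from wild type, of which 2 lie on the minus strand. They were 17.57% of the 74 genes and 0.594% of the other tested genes (odds ratio 35.6, 95% interval 17.0 to 69.8, two-sided Fisher's exact p = 3.15e-15). This test was chosen after the values were seen and counts each gene as independent. Some of the 13 are neighbours, such as AT5G43730 and AT5G43740, so its p-value and interval may be too narrow. The share among the 26 was not tested. Of the 74 tested genes of this class, 15 rose and 37 fell. Genes chosen after their values were seen include TGG2, a myrosinase gene with 54 fragments in cog1-2D and 26431 in wild type, and HR4, a gene of the RPW8 resistance locus with 1 and 1624. The HR4 fragment was in cog1-2D replicate 2, without which HR4 was at least 351-fold lower. In the other direction, ESP, the epithiospecifier gene, had 258 and 2 fragments, both of the latter in wild type replicate 0, without which it was at least 56.5-fold higher. BIP1 and BIP2, near-identical chaperone genes, had 1483 and 28, and 1088 and 24. ESP, BIP1 and BIP2 lie on the minus strand, which was almost unmeasured, so these counts do not show that they were silent in wild type.

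**Figure D2:**
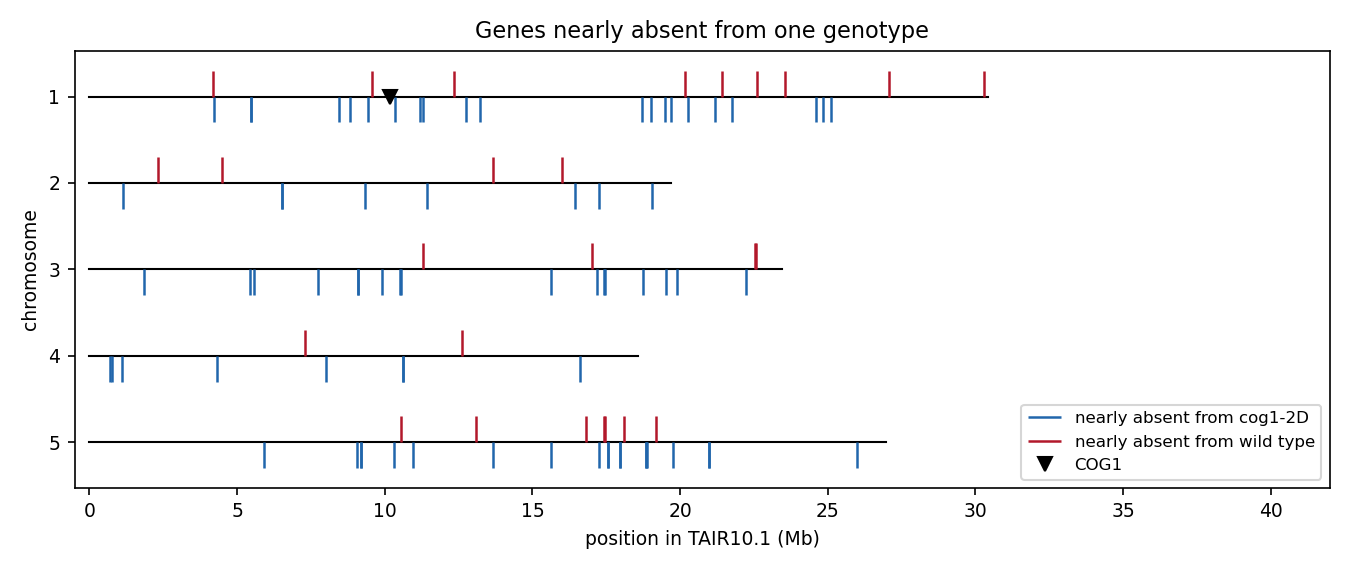
Start positions in TAIR10.1 (Mb) of the 100 genes nearly absent from one genotype, by chromosome, with COG1 as a triangle. Lines below a chromosome mark the 74 genes nearly absent from cog1-2D and lines above it the 26 nearly absent from wild type, and both kinds occur on all 5 chromosomes.

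Class III peroxidases, secreted enzymes that act in cell wall cross-linking and in reactive oxygen metabolism, went both ways. Of 73 family members, 31 were tested, and 5 rose, 9 fell and 17 did not pass. Adjusted over the list alone, 6 rose and 10 fell. PRX39 rose from 48.3 ± 2.6 to 104 ± 11 CPM (SD, n = 3, log2 fold change 1.11 ± 0.08). PRX33 rose by 1.03 ± 0.19 on the log2 scale, from 32.8 to 66.7 CPM, while PRX34 fell by 1.45 ± 0.15, from 202 to 74.1 CPM. PRX33 and PRX34 are adjacent, near-identical copies whose reads the counting could have split, so their opposite changes are uncertain. PRX60 (-0.99 ± 0.17), PRX20 (-0.94 ± 0.13) and PRX7 (-0.71 ± 0.08) also fell. The smaller falls were in PRX50, PRX30, PRX73, PRX44 and PRX31, from -0.59 to -0.32, and the smaller rises in PRX56 (0.44), PRX19 (0.39) and PRX3 (0.30). PRX50 shares much of its sequence with PRX51, its neighbour. The call for PRX31 was lost with any library but wild type replicate 0 left out (edgeR's test, adjusted p = 0.0629 to 0.142). That for PRX56 was lost without cog1-2D replicate 0 or 1 or wild type replicate 0 (edgeR's test, adjusted p = 0.0531, 0.0765 and 0.0686). As a set the family did not pass limma's camera test (adjusted p = 0.686).

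**Figure D3:**
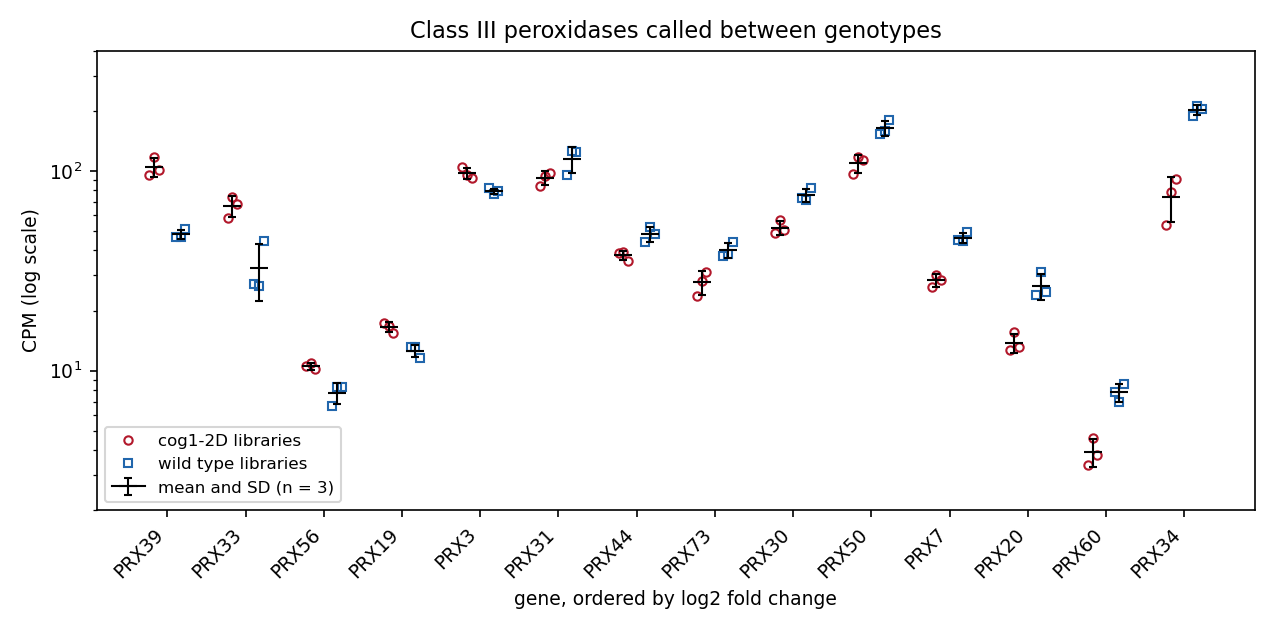
CPM (log scale) of the 14 class III peroxidase genes called between the genotypes, with a point per library and the mean and SD (n = 3) in black. PRX39 stands at 104 CPM in cog1-2D and 48.3 CPM in wild type, and PRX34 at 74.1 and 202 CPM.

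All 8 tested root hair genes fell, over all genes and adjusted over the list alone, with a median log2 fold change of -0.73. PRP1, a cell wall protein gene of root hairs, fell from 11.8 ± 2.1 to 2.77 ± 0.45 CPM. RSL4, a transcription factor that promotes root hair growth, fell by 1.26 ± 0.31 on the log2 scale, a call lost without cog1-2D replicate 1 (-1.10, edgeR's test, adjusted p = 0.0593). EXPA7 fell by 1.01 ± 0.11 and PRP3 by 0.93 ± 0.11, and the list shares PRX44 and PRX73 with the peroxidases. Of 7 suberin genes, 6 fell and 1 did not pass, with the same counts adjusted over the list alone and a median of -0.48. FAR5 and FAR4, neighbouring fatty acyl reductase genes of similar sequence, fell by 1.502 ± 0.09 and 1.40 ± 0.08, the suberin transporter gene ABCG6 by 0.58 ± 0.11, and a further fatty acyl reductase gene, FAR1 (AT5G22500), by 0.48 ± 0.07. In camera, the root hair list passed with adjusted p = 0.00209 and the suberin list with adjusted p = 0.00567. Neither call held in camera with the correlation estimated from the data, where the root hair list had adjusted p = 0.368 with an estimated correlation and the suberin list adjusted p = 0.660 with an estimated correlation.

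Of 8 markers of root tissue, TIP4;1, a vacuolar water channel gene, rose (0.77 ± 0.07), HKT1, a sodium transporter gene, fell (-1.47 ± 0.15), and 6 did not pass. Adjusted over the list alone the counts were also 1 and 1 (camera, adjusted p = 0.810). Of 6 endodermis genes, SCR fell (-0.30 ± 0.09), and 5 did not pass, with 1 fall adjusted over the list alone. The SCR call was lost without cog1-2D replicate 1 or 2 or wild type replicate 0 (edgeR's test, adjusted p = 0.0852, 0.0873 and 0.0629). The median of that list was -0.11 and its mean 0.02 (camera direction down, adjusted p = 0.810). Of 6 lignin genes, PAL3 (-0.52 ± 0.07) and CCR1 (-0.30 ± 0.07) fell and 4 did not pass, against 3 falls adjusted over the list alone (camera, adjusted p = 0.691). The CCR1 call was lost without cog1-2D replicate 1 or 2 (edgeR's test, adjusted p = 0.0606 and 0.0501). Of 4 cutin genes, CYP86A2 rose (0.27 ± 0.09), which was lost adjusted over the list alone, and 4 members were too few for a set test. Its call was also lost with any library but wild type replicate 1 left out (edgeR's test, adjusted p = 0.0682 to 0.168). Of 5 expansin and xyloglucan endotransglucosylase genes, XTH4 rose (0.63 ± 0.17) and XTH23 (-2.92 ± 0.15), XTH9 (-0.40 ± 0.08) and XTH16 (-0.38 ± 0.11) fell, with the same counts adjusted over the list alone (camera, adjusted p = 0.403). Without cog1-2D replicate 1 or 2, the calls of XTH4 (edgeR's test, adjusted p = 0.0651 and 0.0588) and XTH16 (edgeR's test, adjusted p = 0.0849 and 0.0535) were lost.

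Most of the tested genes of glucosinolate and flavonoid synthesis fell. Of 17 glucosinolate genes, 7 lie on the minus strand and 10 were tested. Of the 10, 6 fell and 4 did not pass, against 9 falls adjusted over the list alone, with a median of -0.35. MYB29 fell by 2.02 ± 0.12 on the log2 scale. MAM1, which extends the methionine chain in aliphatic glucosinolate synthesis, fell from 632 ± 86 to 175 ± 25 CPM. On the indolic side, CYP79B2 fell by 1.09 ± 0.08 and the regulator MYB34 by 0.38 ± 0.07. Of 19 flavonoid genes, 9 lie on the minus strand and 8 were tested. Of the 8, 6 fell, 1 rose and 1 did not pass, with the same counts adjusted over the list alone and a median of -0.87. TT8, a regulator of anthocyanin and tannin synthesis, fell by 2.39 ± 0.28, F3'H by 1.42 ± 0.20, F3H by 1.33 ± 0.12 and FLS1 by 0.98 ± 0.12. The member that rose was EGL3 (0.53), a relative of TT8 chosen after its values were seen. In camera, the glucosinolate list passed with adjusted p = 0.00235, and adjusted p = 0.660 with an estimated correlation. The flavonoid list passed camera with adjusted p = 0.0321, and had adjusted p = 0.894 with an estimated correlation. Without cog1-2D replicate 2, the flavonoid list had adjusted p = 0.0523 in camera.

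Most of the tested auxin and shade response genes were higher. Of 12 auxin response genes, 7 lie on the minus strand and 5 were tested. Of the 5, 4 rose and 1 fell, over all genes and adjusted over the list alone. IAA29 rose by 2.08 ± 0.18 on the log2 scale, SAUR15 by 1.24 ± 0.19, IAA19 by 1.02 ± 0.12 and IAA1 by 0.66 ± 0.19. The IAA1 call was lost without cog1-2D replicate 0 or 1 or wild type replicate 2 (edgeR's test, adjusted p = 0.0871, 0.0922 and 0.0554). The member that fell, GH3.5 (-0.58), encodes an enzyme that conjugates auxin to amino acids, and was chosen after its values were seen. The median was 1.02, and the list did not pass camera (adjusted p = 0.151). All 3 tested shade response genes, of 8 in the list, rose, over all genes and adjusted over the list alone. These were IAA29, YUC8, an auxin synthesis gene (1.33 ± 0.21), and ATHB2 (0.69 ± 0.13), and 3 members were too few for a set test. Of 6 brassinosteroid genes, BR6OX2 (0.34 ± 0.10) and BES1 (0.25 ± 0.06) rose and 4 did not pass, with the same counts adjusted over the list alone (camera, adjusted p = 0.198). Without cog1-2D replicate 1 both calls were lost (edgeR's test, adjusted p = 0.0855 for BR6OX2 and 0.0526 for BES1). The BR6OX2 call was also lost without cog1-2D replicate 2 or wild type replicate 0 or 1 (edgeR's test, adjusted p = 0.0897, 0.0573 and 0.0804). Of 14 gibberellin genes, 6 rose, 3 fell and 5 did not pass, against 6 and 4 adjusted over the list alone. GASA6, a gibberellin-induced growth gene, rose from 240 ± 80 to 647 ± 61 CPM, GA2OX8 by 1.33 ± 0.24 and the DELLA repressor gene GAI by 0.49 ± 0.11, and GA2OX6 fell by 0.49 ± 0.12. The gibberellin list had a median of -0.01, a mean of 0.22 and camera direction up (adjusted p = 0.686).

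Photosynthesis, light and clock lists did not pass camera. Of 18 antenna and Rubisco genes, markers of green shoot tissue, LHCB4.2 fell (-0.59 ± 0.10) and 17 did not pass, with 1 fall adjusted over the list alone (camera, adjusted p = 0.686). Of these 18, 11 are minus-strand genes measured at the level of the residue on that strand. Of 7 chlorophyll genes, PORB (0.73 ± 0.16) and PORC (0.29 ± 0.06), which encode protochlorophyllide reductases, rose, and GLK2, a regulator of chloroplast development, fell (-0.73 ± 0.08). The counts adjusted over the list alone were the same, and 4 did not pass (camera, adjusted p = 0.686). Minus-strand genes, measured only at the level of the residue, made up 3 of those 4. Of 11 light signalling genes, PIF3 rose (0.40 ± 0.08), PHYB (-0.35 ± 0.06) and ELIP2 (-0.99 ± 0.22) fell, and 8 did not pass, with the same counts adjusted over the list alone. That list had a median of 0.02, a mean of -0.09 and camera direction up (adjusted p = 0.953). Of 11 clock genes, RVE4 rose (0.21 ± 0.07), PRR9 fell (-0.57 ± 0.13) and 9 did not pass, and adjusted over the list alone only PRR9 remained (camera, adjusted p = 0.719). The RVE4 call was lost in 9 settings, among them the fits without cog1-2D replicate 0 or 1 or wild type replicate 0 or 2 (edgeR's test, adjusted p = 0.119, 0.167, 0.122 and 0.0720). The only flowering gene tested, SVP, had a log2 fold change of 0.03 ± 0.10 and did not pass, over all genes or adjusted over the list alone.

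Stress hormone and defence lists held strong single genes but did not pass camera. Of 7 abscisic acid response genes, 4 fell and 3 did not pass, against 5 falls and 1 rise adjusted over the list alone, with a median of -0.73 (camera, adjusted p = 0.151). KIN1 fell by 2.93 ± 0.39, RD29A by 0.86 ± 0.06, KIN2 by 0.73 ± 0.19 and ABF3 by 0.28 ± 0.07 on the log2 scale. Without cog1-2D replicate 2, KIN1 had a log2 fold change of -3.89. The KIN2 call was lost without cog1-2D replicate 0 and the ABF3 call without cog1-2D replicate 1 (edgeR's test, adjusted p = 0.0591 and 0.0549). KIN1 and KIN2 are tandem copies, so the division of fragments between them is uncertain. Of 7 jasmonate genes, 3 fell and 4 did not pass, with the same counts adjusted over the list alone (camera, adjusted p = 0.151). AOC2, of a tandem family of allene oxide cyclases, fell from 163 ± 46 to 25.5 ± 13.6 CPM, and JAZ7 (-1.34 ± 0.42) and JAZ9 (-0.73 ± 0.09) also fell. The JAZ7 call was lost with any library but wild type replicate 2 left out (edgeR's test, adjusted p = 0.0788 to 0.121). All 7 tested salicylic acid and defence genes, of 15 in the list, changed, with 3 rising and 4 falling, also adjusted over the list alone (camera, adjusted p = 0.803). ALD1, a gene of pipecolic acid synthesis, rose by 2.18 ± 0.33. EDS5, a salicylic acid exporter gene, fell by 1.40 ± 0.12, PR5 by 1.31 ± 0.18 and CBP60G by 1.29 ± 0.32. The other members that rose were PBS3 (1.03) and ICS1 (0.62), chosen after their values were seen.

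Of 12 antioxidant genes, CAT3, a catalase gene, rose from 1827 ± 339 to 2957 ± 127 CPM and CSD3 rose (0.17 ± 0.06), a call lost with any library but wild type replicate 2 left out (edgeR's test, adjusted p = 0.0767 to 0.126). VTE2 (-0.73 ± 0.08) and CAT1 (-0.41 ± 0.11) fell and 8 did not pass, with the same counts adjusted over the list alone. The CAT1 call was lost without cog1-2D replicate 0 or wild type replicate 1 or 2 (edgeR's test, adjusted p = 0.0673, 0.0623 and 0.0726). The median was -0.02, the mean -0.04 and the camera direction up (adjusted p = 0.908). Of 10 iron deficiency genes, IMA3 fell (-1.67 ± 0.56) and 9 did not pass, and the call was lost adjusted over the list alone and with any library but wild type replicate 1 left out (edgeR's test, adjusted p = 0.0554 to 0.145). Without wild type replicate 0 its log2 fold change was -0.94. The median of that list was 0.13, the mean -0.25 and the camera direction up (adjusted p = 0.810). Of 6 phosphate starvation genes, PAP17 (-1.28 ± 0.40) and PHT1;4 (-1.01 ± 0.16) fell and 4 did not pass, with 2 falls adjusted over the list alone (camera, adjusted p = 0.780). The PAP17 call was lost in 7 settings, among them the fits without cog1-2D replicate 0, 1 or 2 (edgeR's test, adjusted p = 0.0731, 0.105 and 0.0858), and without wild type replicate 0 its log2 fold change was -0.57. Of 5 touch, cold and wound genes, a check on handling, TCH3 (-0.75 ± 0.10) and WRKY33 (-0.48 ± 0.13) fell and 3 did not pass, with 2 falls adjusted over the list alone (camera, adjusted p = 0.726). The WRKY33 call was lost without cog1-2D replicate 2 (edgeR's test, adjusted p = 0.0755). None of 5 heat shock genes passed edgeR's test, over all genes or adjusted over the list alone, with 1 at an unadjusted p under 0.05 and 0 called by DESeq2. Without wild type replicate 2, HSP17.6C passed (-1.37, edgeR's test, adjusted p = 0.0425). Their median was 0.02, their mean -0.21 and the camera direction down (adjusted p = 0.810). Of 2 seed maturation genes, 0 passed edgeR's test and 1 fell adjusted over the list alone. PER1 had a log2 fold change of -2.24 ± 0.81 (edgeR's test, adjusted p = 0.0566), with 1 gene of the list at an unadjusted p under 0.05 and 1 called by DESeq2. It had 1, 1 and 13 fragments in cog1-2D and 47, 16 and 11 in wild type. It passed without cog1-2D replicate 2 (-4.40, edgeR's test, adjusted p = 0.0136) or wild type replicate 2 (-2.57, adjusted p = 0.0404), and had -1.44 without wild type replicate 0. Of 4 reference genes, 0 passed, also adjusted over the list alone, with 0 at an unadjusted p under 0.05 and 0 called by DESeq2. Their values ran from -0.11 ± 0.06 for EF1A to 0.15 ± 0.07 for UBC21.

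**Figure D4:**
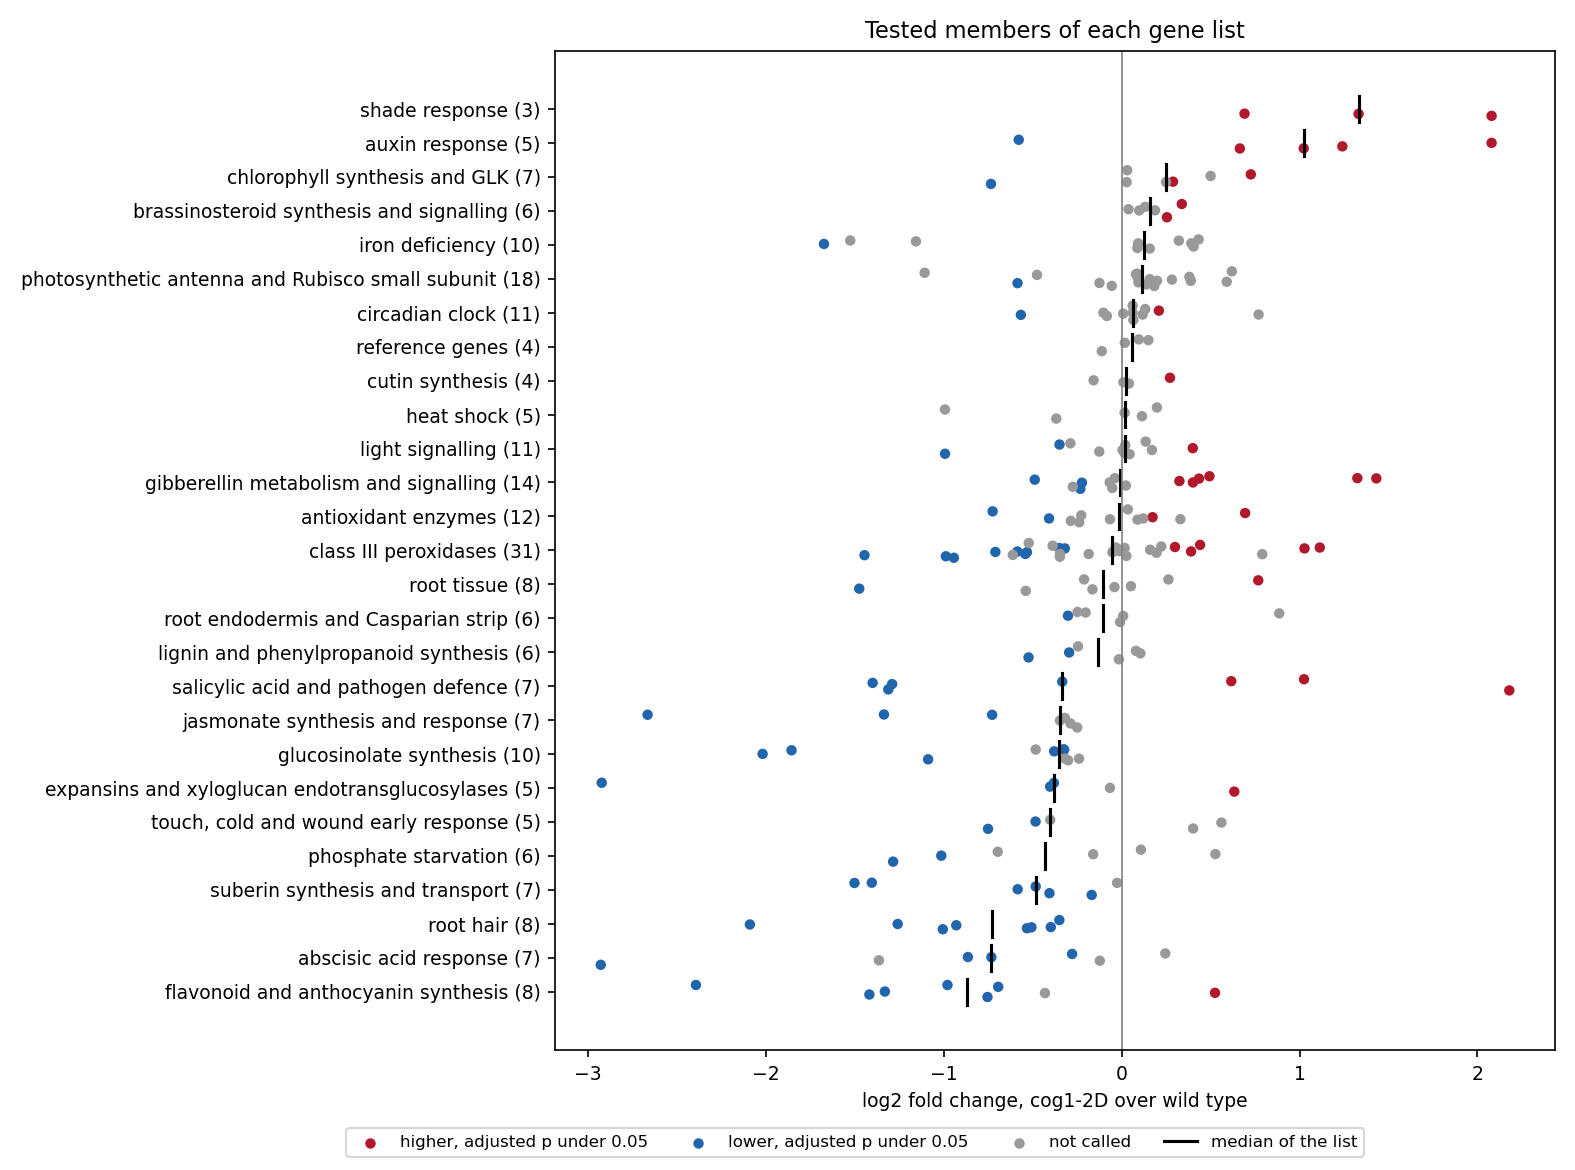
Log2 fold changes (cog1-2D over wild type) of the tested members of each list with at least 3, a point per gene coloured by edgeR's call at an adjusted p of 0.05, and the median as a black line; the number tested stands in parentheses. The root hair points all lie below 0, with a median of -0.73, and the shade response points all lie above it.

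The authors' deposited table of Cuffdiff calls listed 3124 genes, of which 1360 were higher and 1764 lower in cog1-2D. Of these calls, 1224 higher and 1602 lower genes were also called here in the same direction, where independent lists would share 218.5 and 345 genes. None had the opposite direction in edgeR. Both sets of calls come from the same libraries, so the overlap compares methods only. The deposited table held 3088 plus-strand and 26 minus-strand genes, the same gap as in the counts.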

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

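Of the settings reported here, plus-strand genes only and leaving out genes nearly absent from one genotype were chosen after seeing the data. The counts of 1686 higher and 2066 lower genes stayed within 1.5 times under every setting tried, at 1129 to 1896 and 1554 to 2303. Upper-quartile factors gave 1896 and 1936, DESeq2 1272 and 1702, and leaving out a library 1129 to 1488 and 1554 to 1890. Plus-strand genes only gave 1706 and 2128, and leaving out the genes nearly absent from one genotype 1638 and 1990. Requiring a mean of at least 50 counts left 140 genes higher and 366 lower by 2-fold or more, against 290 and 596, with fewer genes tested. With an estimated correlation, camera's adjusted p was 0.368 for root hair, 0.660 for suberin and for glucosinolates, and 0.894 for flavonoids. With fry, RLE factors, no low-count filter, the replicate block, plus-strand genes only, without the nearly absent genes and with each library left out, these 4 lists passed, except flavonoids without cog1-2D replicate 2 (leave-one-out range 0.0125 to 0.0523). In fry, adjusted p was 0.00992 for abscisic acid and for auxin, 0.0110 for lignin, 0.0203 for expansins, 0.0205 for jasmonate and 0.0258 for brassinosteroids. Without a low-count filter, auxin had adjusted p = 0.0251 in camera. With the filter and an estimated correlation, its adjusted p in camera was 0.660. The cause of these differences was not tested. Of the authors' genes changed by 2-fold or more, 257 higher and 520 lower were shared, against chance values of 7.68 and 30.8. The replicate block gave 1863 higher and 2230 lower genes, 4093 in all with 3632 of the 3752 shared. It ended no set test call, removed the call of IMA3 and added that of AT1G29040. Same-numbered libraries had correlations of deviations of -0.0146, -0.0162 and 0.106, and not every library correlated best with its own number. Deviations from group means constrain each other, so these values do not decide whether the numbers pair the libraries. Of 119 named genes, none reversed a called direction. The 23 that lost their call in at least 1 setting were ABF3, AT1G29070, BES1, BR6OX2, CAT1, CCR1, CSD3, CYP86A2, GA2OX6, IAA1, IMA3, JAZ7, KIN2, PAP17, PRX19, PRX31, PRX56, RSL4, RVE4, SCR, WRKY33, XTH16 and XTH4. All of these except GA2OX6 and PRX19 lost it with a library left out. Few fragments on the minus strand limit what can be said of COG1, PRX25 and PRX71, which edgeR did not call without a low-count filter, and PRX2 had 0.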

Other observations

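The enrichment tests and the tests of explanations below were chosen only after the result was seen, except that of fragments on overlapping loci and the splits for the gene lists.

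Among all called plus-strand genes, defence genes stood out on the lower side and a family of small auxin-induced genes on the higher side. Of 142 tested genes annotated with defense response, 66 fell (46.5%, against 20.4% of all tested genes; one-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 7.25e-10). Without the genes nearly absent from one genotype, that term still passed (Fisher's exact test, adjusted p = 2.78e-05). That removal covered only genes with at least 5 CPM in one genotype. Less abundant genes with 0 fragments in cog1-2D stayed in, such as AT5G48780 (96 in wild type) and RLP50 (95 in wild type). Both were chosen after their values were seen. The repeat therefore does not separate the term from genes absent from one genotype. Innate immune response passed with 27 of 49 genes (Fisher's exact test, adjusted p = 1.14e-05, and 0.0149 without the nearly absent genes). AT5G48780 stayed in that repeat too. Apoptosis (33 of 66), signal transduction (42 of 114) and response to cold (24 of 61) passed on the lower side but not without the nearly absent genes. These terms are not independent, since they share genes. AT5G46510, AT4G19500 and AT5G51630 stand under defense response, innate immune response, apoptosis and signal transduction. DAR4 stands under defense response and response to cold. Of 12 genes of the CC-NBS-LRR family, which passed but kept too few members for a test without the nearly absent genes, 9 fell, among them ADR1 (-0.54 ± 0.12), a helper immune receptor gene chosen after its values were seen. Of the genes annotated with response to cold, ESM1, a modifier of glucosinolate breakdown, and JAL33, a jacalin-related lectin, fell from 365 ± 33 to 72.9 ± 4.5 CPM and from 335 ± 30 to 11.3 ± 0.9 CPM (SD, n = 3), both chosen after their values were seen.

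Of 35 tested genes of the SAUR-like family, whose products promote cell expansion, 18 rose (51.4%, against 16.5% of all tested genes; Fisher's exact test, adjusted p = 0.0002). The median log2 fold change of the 35 was 0.72. SAUR23 rose by 1.80 ± 0.24, SAUR27 by 1.66 ± 0.17 and SAUR24 by 1.25 ± 0.20, chosen after their values were seen. AT1G29490, also chosen so, rose by 2.15 ± 0.27. It starts at 10319732 on chromosome 1, the chromosome of COG1 (10183390 to 10184512). Whether its place near COG1 bears on its rise was not tested. Several of these genes are tandem copies of similar sequence, so single values are uncertain. The oxidation reduction term also passed on the higher side, with 67 of 262 genes (Fisher's exact test, adjusted p = 0.0055), of which CYP71B9, chosen after its values were seen, rose by 2.94 ± 0.30. In all, 2 of 208 terms passed on the higher side and 6 on the lower, where several terms share genes. CRC, a cruciferin seed storage gene not tested, was chosen after its values were seen. It had 369 fragments in cog1-2D replicate 2 and 0 in the other cog1-2D libraries, with 10, 1 and 0 in wild type.

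The near absence of minus-strand genes is a property of the deposited counts in both genotypes. Shallow sequencing is argued against, since the share of protein-coding genes with 60 or more fragments differed by 70.9 percentage points between the strands. Assignment to overlapping plus-strand loci is also argued against, since 731 such non-coding loci held 0.0819% of all fragments. The gap spans 13666 protein-coding genes, with a median of 1 fragment against 985 on the plus strand. A gap that follows the reference strand in both genotypes argues against low expression of these genes as its source. A loss of fragments of one genome strand before the deposited counts stays open, and the step where it would arise was not tested. Minus-strand antenna and Rubisco genes had 0.151% of the median CPM of the plus-strand members, but the same gap fixes that value, so it does not test the loss.

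Genes nearly absent from one genotype may reflect sequence differences between the line and the reference rather than the action of COG1. A deletion or rearrangement around the tagged locus is argued against as the source of the 74, since 28.4% of them lie on chromosome 1, which holds 26.7% of the tested genes. A strain variant against the reference stays open, as the enrichment of immune receptor genes, a class that varies between accessions, had an odds ratio of 35.6, and 3 of the 26 genes nearly absent from wild type were of that class too, 2 of them on the minus strand. Regulation by COG1, alone or with the line's background, also stays open and was not tested, since every cog1-2D library shares both. The same holds for the other genes called between the genotypes, among them those of glucosinolate synthesis.

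Lower root hair and suberin transcripts could follow from a smaller share of root tissue in the cog1-2D seedlings. That stays open. The 14 root tissue and endodermis genes had a median log2 fold change of -0.10, against -0.53 for the 15 root hair and suberin genes (two-sided permutation test of the means, p = 0.00268). The gap of 0.43 between the medians was smaller than the SD of 0.56 among the 14 genes, which went both ways, and the lists compared were chosen because they fell, so this test decides nothing. Changes in root hair or suberin cells themselves, whether from COG1 or from the line's background, also stay open and were not tested.

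The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. The real split called 3752 genes in edgeR and 1 of the 10 splits gave as many, with 0 as the highest of the others. Each of the others put libraries of both genotypes in both groups. The genotype difference then lay within the groups, so those 0 calls do not measure chance. Those other splits had 52 to 429 genes at an unadjusted p under 0.05, and DESeq2 called at most 2. For the gene lists, the real split passed 4 in camera with the preset correlation, the highest other split passed 5, and 7 of the 10 splits passed at least 4. The mixed splits keep part of the genotype difference, so their passes give no error rate for camera.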
